A study of Homo sapiens with 4 samples.

How the data were processed

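Gene expression was measured by RNA sequencing in HCT116, a human colorectal carcinoma cell line. The series holds 4 libraries, 2 from control cells and 2 from cells in which RALY was knocked down. RALY is an RNA-binding protein of the hnRNP family related to HNRNPC. Per the labels' protocols, cells received lentivirus carrying a short hairpin RNA against RALY or a nonsilencing hairpin for 72 h, total RNA was extracted, and libraries were made with a standard Illumina protocol. Other labels call the control cells untreated or wild type, so whether the controls carried the nonsilencing hairpin is not settled by the sources used here. The hairpin sequence and the number of hairpins are not given in the sources used here. One label numbers the cell line differently from library to library, while the cell line entry is HCT-116 for all 4 libraries. Groups and replicate numbers were taken from the sample titles. No label says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

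The deposited values are whole-number counts of reads per gene, 1 table per library, with the exons, strand and length of each gene in the layout that featureCounts writes, per the file headers. Per the submitters' processing notes, the tools were HISAT2 2.0.4, SAMtools, featureCounts and Subread and the genome build was GRCh38; no role, setting or order is recorded for them. Whether strand was used in counting, and whether reads sharing a position were removed, is not given in the sources used here. Each table lists 58884 Ensembl genes, of which 58472 were found in GENCODE release 44 and 58458 of these lay at an overlapping place on the same chromosome. Gene names, biotypes, canonical transcript lengths and GC content were taken from that release. Coordinates are those of the deposited tables on GRCh38, counted from 1.

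Library totals were 13360007 and 16847520 counts in the controls and 16493967 and 14762755 in the knockdown libraries, so that 3 counts, the floor used for a gene with no count, correspond to between 0.178 and 0.225 CPM (counts scaled to 1e6 per library). Floors cover counting error only. Counts of abundant genes appeared to level off relative to transcript length. Among the genes looked at, counts per base ran from 0.934 for EEF1A1 to 2.07 for GAPDH. The totals are therefore not a plain measure of depth, and fold changes of abundant genes can be compressed. Occupancy, the mean count divided by 2 times the canonical transcript length, is used as a measure of the levelling off. The 2 libraries of each group differed by more than counting noise (chi-square per degree of freedom 5.1 for the controls and 9.32 for the knockdown), a value that also takes in differences from levelling off, so it does not tell whether they are technical repeats.

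Genes were tested with edgeR 4.0.16 under R 4.3.3. Genes with too few counts were removed with filterByExpr, leaving 19686 genes, libraries were scaled with TMM factors, and a robust quasi-likelihood model with a term for the group was fitted to the counts and tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. CPM values use TMM-scaled totals. Log2 fold changes are knockdown over control with their standard error (SE). Lists of genes were tested with camera of limma 3.58.1, which compares a list with the other genes, at a preset correlation between genes of 0.01, for lists with at least 5 tested members and with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, which rests on 2 residual degrees of freedom, and with fry, which asks whether a list moves on balance in 1 direction.

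The groups, the tests, 35 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named RALY first, then the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the groups. For each list it named up to 4 called members with the smallest p in the more frequent direction and up to 2 in the other, or up to 2 members with the smallest p, as values, where none was called. It also named the reported RALY targets, HNRNPC and RALYL, EIF2S2, whose span overlaps that of RALY, and AHCY and ASIP, which lie near it. Not every gene so chosen is discussed below, and some are not reported here. Of the list members, DDX58 was matched as RIGI, and SOD2, H2AC18, H3C2 and H3C3 were not matched.

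The alternatives fixed beforehand were DESeq2 size factors or plain totals in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, and a test against a minimum fold of 1.2. Alternatives added after the data were seen were a correction of the counts for levelling off tested with limma-trend on log2(CPM + 1), offsets that follow the count per base, offsets that follow GC content and transcript length, and the last together with the replicate block. The correction left out genes with an occupancy, as a fraction, of 0.9 or more in any library. The scripts were tested on simulated data with 200 changed genes drawn on the real means and library sizes. For this comparison edgeR recovered 71.7% of the 99 tested genes changed 2-fold and 39.4% of the 99 tested genes changed 1.5-fold. Among 18918 genes tested, 4 unchanged genes were called. These simulated counts did not level off, and genes of low count or high occupancy were not among those changed. Far fewer genes were changed than were called in the real data, so these shares are not the power of the real comparison. Gene positions were compared to find named genes that share exon bases with another gene, and bootstrap intervals, drawn over genes, are at 95% and cover the spread among genes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.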

Results

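Gene-level RNA sequencing counts were compared between 2 control libraries and 2 RALY knockdown libraries of HCT116 colorectal carcinoma cells. The single comparison of the design asks which transcripts differ when RALY, an hnRNP family RNA-binding protein, is depleted for 72 h. Totals ran from 13360007 to 16847520 counts per library.

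RALY itself was lower in both knockdown libraries. The gene (ENSG00000125970, chromosome 20, positions 33993646 to 34108308, GRCh38) had 1903 and 2132 counts in the controls and 634 and 522 in the knockdown libraries. Its level was 134 ± 14.8 CPM in the controls and 37.3 ± 3.15 CPM in the knockdown (SD, n = 2 each), so 27.9% of the control level remained. The log2 fold change was -1.84 (SE 0.127, edgeR quasi-likelihood adjusted p = 6.59e-06). EIF2S2, whose span overlaps that of RALY on the opposite strand without shared exon bases, fell by 0.35 on the log2 scale (edgeR adjusted p = 0.0418). Of the nearby genes on chromosome 20, AHCY had a log2 fold change of -0.02 (edgeR adjusted p = 0.944), and ASIP had no count in any library. HNRNPC, the closest relative of RALY measured, had a log2 fold change of 0.06 (edgeR adjusted p = 0.78). AHCY and HNRNPC had occupancies of 64.4% and 58.4%, where fold changes can be compressed. RALYL had 1 count in 1 control library and none elsewhere and was not tested.

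After RALY knockdown, 15 of 19 TGF-beta and YAP targets, 16 of 21 mesenchymal and matrix genes and 11 of 23 immediate early genes rose, while 0, 2 and 1 of them fell. Camera called these lists at its preset correlation, but not with an estimated correlation (camera adjusted p = 0.397, 0.397 and 0.986). Fry called the TGF-beta and YAP targets (fry adjusted p = 0.0456) and no other list. In the ATF4 and amino acid response 17 of 28 genes fell, in cholesterol synthesis 6 of 25 fell, and among epithelial junction and identity genes 9 of 27 fell and 2 rose. Camera called these lists too at its preset correlation, and not with an estimated correlation (camera adjusted p = 0.397, 0.986 and 0.986). With 2 residual degrees of freedom, the estimated correlation left no list called. The ATF4 list lost its call there with an estimated correlation of 0.0208, near the preset 0.01. That was the lowest value among the called lists. The immediate early and cholesterol lists had 0.378 and 0.619, and cytosolic ribosomal proteins 0.841. Adjusted p-values of such lists at the preset correlation may be too small. With so few degrees of freedom the estimated setting cannot decide which lists moved. SMAD7, an inhibitor induced by TGF-beta, rose 8.41-fold, from 7.73 ± 2.57 to 65.9 ± 2.90 CPM (SD, n = 2 each). CCN2, a matrix protein and YAP target, rose 5.84-fold from 19.9 ± 5.18 to 117 ± 5.64 CPM. TRIB3, a pseudokinase induced by ATF4, was 2.69-fold lower after knockdown, with 96.2 ± 9.39 CPM in the controls and 35.7 ± 3.69 CPM in the knockdown.

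Of 19686 genes tested, 2470 were higher and 2578 lower in the knockdown, or 25.6% in all (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). More than 2-fold, 986 were higher and 846 lower. In each of the 5048 called genes the groups did not overlap, as in 63.6% of all tested genes, where chance gives 33.3%. The number of calls fell when either control was left out and rose when either knockdown library was left out. Such a fit takes its spread from the remaining pair, and the knockdown pair differed more (chi-square per degree of freedom 9.32 against 5.1 for the controls). The fall in calls therefore does not show that the differences rest on the controls. The same applies to counts of calls without 1 control given below. Among called genes named by the rule, 81 of 137 lost their call without control replicate 1 and 75 without control replicate 2, and none changed direction.

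**Figure D1:**
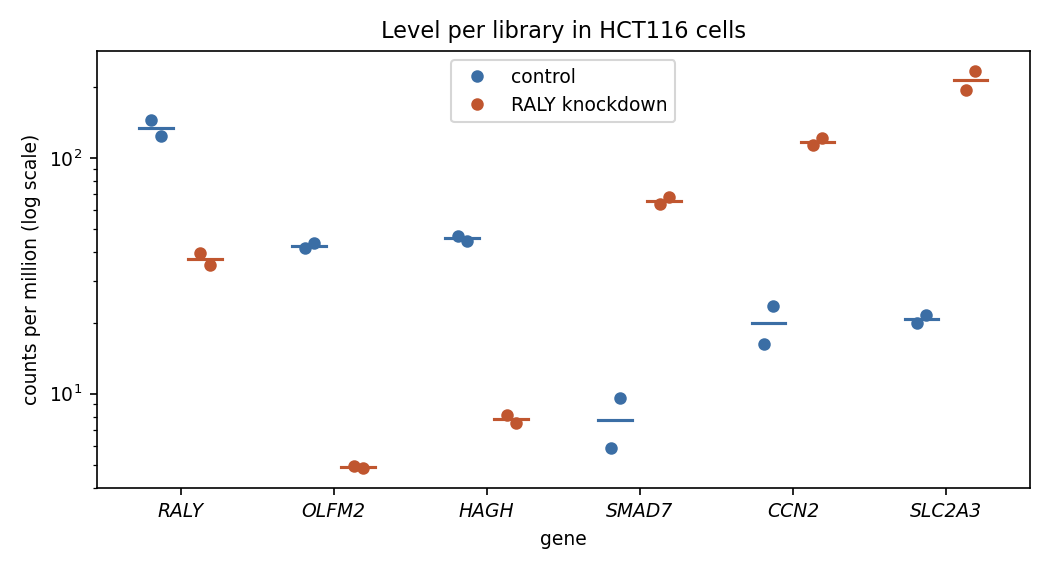
Level of 6 genes in each library, in CPM on a log scale; points are libraries, bars are the means of 2 libraries, blue is control and orange is RALY knockdown. RALY, OLFM2 and HAGH lie lower in both knockdown libraries, and SMAD7, CCN2 and SLC2A3 lie higher in both.

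Among protein-coding genes with a mean of at least 5 CPM, the largest rise was that of EID3, a homologue of a subunit of the SMC5/6 complex, with 1.37 ± 0.760 CPM in the controls and 20.2 ± 0.260 CPM in the knockdown (log2 fold change 3.82, SE 0.312, edgeR adjusted p = 2.15e-05). SLC2A3, a glucose transporter, rose from 20.7 ± 1.13 to 214 ± 28.2 CPM (log2 fold change 3.37, SE 0.137, edgeR adjusted p = 1.41e-07). SLC2A3 has a near-identical paralog, SLC2A14, with 0 and 3 counts in the controls and 35 and 34 in the knockdown, and reads may be split between them. Large rises were also seen for SMAD7, EDN1, which encodes endothelin, the actin-binding ENC1, the kinase gene DCLK1, PKD1L1, CCN2, the keratin KRT80, TCP10L and PRF1, which encodes perforin, with log2 fold changes between 2.41 and 3.07. Leaving out 1 library moved 2 of these values by more than 1.5-fold: EID3 was 4.57 on the log2 scale without control replicate 2, and TCP10L was 3.09 without control replicate 2 and 1.38 without knockdown replicate 2. TCP10L was not called without control replicate 1 or 2 (edgeR adjusted p = 0.132 and 0.0747).

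Among the genes with large falls, OLFM2, a secreted olfactomedin protein, had 42.5 ± 1.31 CPM in the controls and 4.88 ± 0.0616 CPM in the knockdown (log2 fold change -3.12, SE 0.183, edgeR adjusted p = 2.85e-06). PAQR8, EVI5L, the calcium channel TRPV4, the actin-associated SYNPO, LYRM9, ABHD14A, the glyoxalase HAGH, the potassium channel KCNG1, the transcription factor CREB3L3 and C1QL1 also fell, with log2 fold changes between -3.10 and -2.44. ABHD14A was at -3.27 on the log2 scale without knockdown replicate 1. Of the 146 named genes, 12 share over 20% of their exon bases with another gene on either strand, and their counts are uncertain: LYRM9, ABHD14A, TCP10L, ASNS, ATP5ME, HNRNPUL2, ACTA2, FAS, H1-10, IRF9, AXIN2 and RNF43.

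Camera called 13 of the lists at the preset correlation, 8 towards higher and 5 towards lower levels, and called none with an estimated correlation. The latter setting has 2 residual degrees of freedom, so its values are given below without a conclusion. Of the 19 tested TGF-beta and YAP targets, 15 rose and none fell over all genes tested, and 16 rose when adjusted over the list alone (median log2 fold change 1.17, camera adjusted p = 4.55e-26, adjusted p = 0.397 with an estimated correlation). They included SKIL, a SMAD corepressor, at 1.67, and CCN1, a matricellular YAP target, at 1.61 on the log2 scale. Of 21 mesenchymal and matrix genes, 16 rose and 2 fell, with 17 and 2 adjusted over the list alone (median 1.22, camera adjusted p = 2.52e-15, adjusted p = 0.397 with an estimated correlation). THBS1, which encodes thrombospondin, rose by 1.58 on the log2 scale, while the smooth muscle actin gene ACTA2 fell by 0.85 and the metalloproteinase gene MMP14 fell by 0.41. CCN1 and CCN2 belong to both lists.

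Fibroblast markers gave 1 called gene of 4 tested, COL6A3, which rose by 0.70 on the log2 scale, and 2 higher and 1 lower adjusted over the list alone. The highest of them, COL1A1, had 121 ± 13.8 CPM in the controls and 95.5 ± 21.1 CPM in the knockdown (log2 fold change -0.34, edgeR adjusted p = 0.107). Leukocyte markers gave 1 higher of 9 (ITGAM; 1 adjusted over the list alone, camera adjusted p = 0.759), with CD68 highest at 29.7 and 22.8 CPM. Markers of HEK293T, a line used to package lentivirus, gave 1 higher of 7 (NEFH; 1 adjusted over the list alone, camera adjusted p = 0.358), with CRABP2 highest at 88.8 and 89.5 CPM. Embryonic and neural genes gave 1 higher of 6 (PAX6; 1 adjusted over the list alone, camera adjusted p = 0.358), with TUBB3 highest at 130 and 121 CPM in controls and knockdown.

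Of 23 immediate early and MAPK feedback genes, 11 rose and 1 fell, with 14 and 1 adjusted over the list alone (median 0.36, camera adjusted p = 0.000315, adjusted p = 0.986 with an estimated correlation). The transcription factor genes FOSB, JUN, FOS and EGR3 rose by 1.45, 0.94, 1.11 and 1.34 on the log2 scale, and SPRED2 fell by 0.37. Of 16 NF-kB and inflammatory genes, 7 rose and none fell, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.986 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, rose 2.17-fold and the chemokine gene CXCL8 rose 2.60-fold. Of 17 Wnt targets, 5 rose, with 6 adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.986 with an estimated correlation). Among them were AXIN2 and RNF43, both negative regulators of Wnt signalling, at 1.26 and 1.17 on the log2 scale. Counts of these 2 genes are uncertain, as they share 25.2% and 73.9% of their exon bases with other genes. NKD1 and EPHB3 rose by 0.97 and 1.14 on the log2 scale. The Wnt list lost its call without knockdown replicate 2 (camera adjusted p = 0.111) and with saturation-corrected counts (camera adjusted p = 0.0753).

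Of 26 apoptosis regulators, 9 rose and none fell, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00938, adjusted p = 0.986 with an estimated correlation; camera adjusted p = 0.0535 with saturation-corrected counts). The proapoptotic genes BCL2L11, PMAIP1 and BMF rose by 0.94, 0.82 and 1.46 on the log2 scale, and the antiapoptotic BCL2 rose by 1.13. Of 20 hypoxia genes, 6 rose and 3 fell, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0067, adjusted p = 0.986 with an estimated correlation), and the call was lost without knockdown replicate 2 (camera adjusted p = 0.175) and with saturation-corrected counts (camera adjusted p = 0.258). SLC2A3, the lipase inhibitor gene ANGPTL4 (1.76 on the log2 scale) and the peptide hormone gene ADM (1.32) rose, and NDRG1 fell by 0.50. Cytosolic ribosomal protein genes had a median occupancy of 87.15%, where counts had levelled off. Their median log2 fold change was 0.14 over 74 genes. Of these, 2 rose, RPL22 by 0.43 among them, and none passed when adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.986 with an estimated correlation). That call was lost without control replicate 2 (camera adjusted p = 0.951), without knockdown replicate 2 (camera adjusted p = 0.111) and with GC and length offsets (camera adjusted p = 0.211).

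Of 28 genes of the ATF4 and amino acid response, 17 fell and none rose, with 17 adjusted over the list alone (median -0.42, camera adjusted p = 2.55e-08, adjusted p = 0.397 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, fell by 1.03 on the log2 scale, the asparagine synthetase gene ASNS fell by 0.83 and the transfer RNA synthetase gene CARS1 fell by 0.77. Of 25 cholesterol synthesis genes, 6 fell, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00603, adjusted p = 0.986 with an estimated correlation), including SREBF2, the transcription factor of the pathway, by 0.92 and MVD by 0.77. Of 62 nuclear genes of electron transport complexes, 7 fell, with 5 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.986 with an estimated correlation), among them NDUFA5 by 0.60 and SDHC by 0.49. This is no larger a share than the 2578 lower of all 19686 genes tested, so the count alone shows no excess of falling members. Both lists lost their call without control replicate 1 (camera adjusted p = 0.186 and 0.26).

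Of 17 tricarboxylic acid cycle genes, 3 fell (SUCLG2 by 1.08, OGDH by 0.58 and SUCLA2 by 0.56), with 3 adjusted over the list alone (camera adjusted p = 0.0396, adjusted p = 0.986 with an estimated correlation). Of 27 epithelial junction and identity genes, 9 fell and 2 rose, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0396, adjusted p = 0.986 with an estimated correlation). The junction genes TJP3 and PKP3 fell by 1.86 and 1.13, the protease gene ST14 by 1.14 and the epithelial transcription factor gene GRHL2 by 1.49, while TJP1 and MUC1 rose by 0.61 and 0.83 on the log2 scale. Calls of both lists were lost in several settings, without control replicate 1 (camera adjusted p = 0.186 and 0.113) and with saturation-corrected counts (camera adjusted p = 0.0535 and 0.178) among them.

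**Figure D2:**
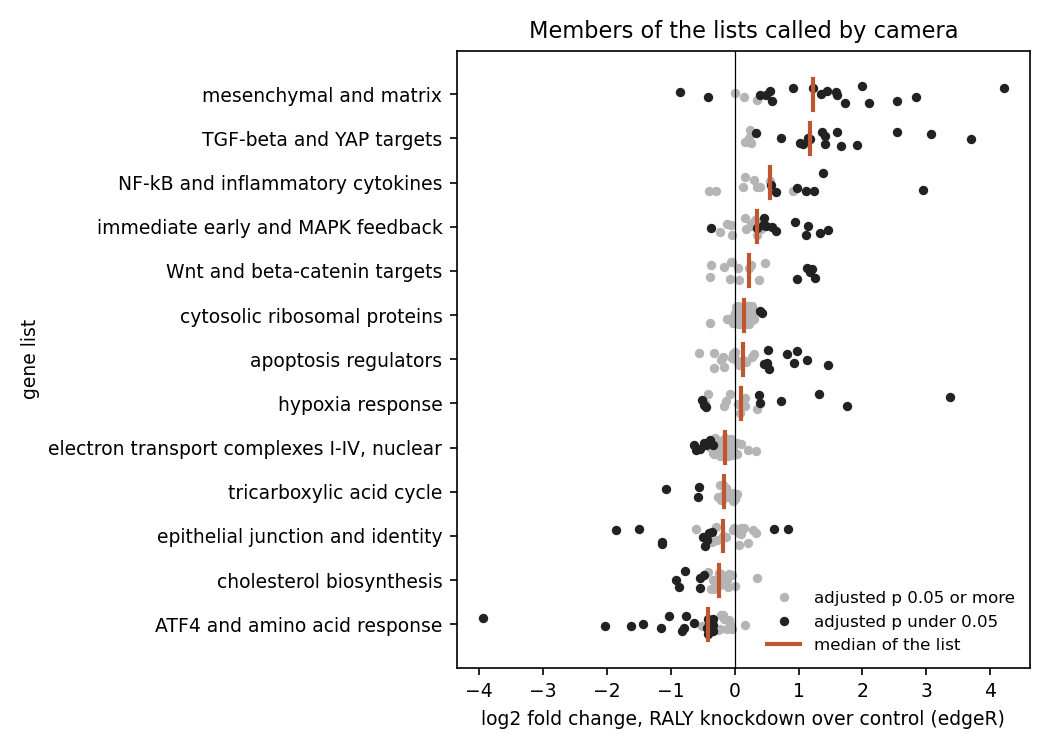
Log2 fold change of each tested member of the 13 lists called by camera at the preset correlation, knockdown over control; black points passed an adjusted p of 0.05 in edgeR, grey points did not, and orange bars are list medians. Medians run from -0.42 for the ATF4 and amino acid response to 1.22 for mesenchymal and matrix genes.

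The remaining lists were not called by camera. In the hnRNP family, PTBP2 and PTBP3, splicing regulators, rose 2.29-fold and 1.41-fold and HNRNPUL2 and HNRNPM fell by 0.83 and 0.46 on the log2 scale, out of 27 members (2 and 2 also adjusted over the list alone, camera adjusted p = 0.874). The median occupancy of this list was 52.2%, where fold changes can be compressed. None of 35 SR protein and core spliceosome genes was called by edgeR, over all genes or adjusted over the list alone; 3 had an unadjusted p under 0.05, DESeq2 called 0, saturation-corrected counts called 1, and camera gave an adjusted p of 0.881. The smallest p belonged to SNRPA and SNRPE (log2 fold changes -0.30 and -0.33, edgeR adjusted p = 0.0785 and 0.0998), and each was called as lower in some alternatives. None of 13 mitochondrially encoded genes was called by edgeR, over all genes or adjusted over the list alone, none had an unadjusted p under 0.05, DESeq2 called 0, and camera gave an adjusted p of 0.761; their median occupancy was 88.3%, where counts had levelled off. Of 27 microRNA biogenesis and m6A genes, 6 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0621), among them TNRC6A, a scaffold of microRNA silencing, by 1.10 and DICER1 by 0.58, with METTL3 lower (log2 fold change -0.34).

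Of 41 S phase and DNA replication genes, 2 rose and 8 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.16). CCNE1 fell by 0.72 and UHRF1 by 0.68, while CCNE2 rose by 0.68 on the log2 scale. Of 38 mitosis genes, 3 fell, CCNF, CDC25B and MAD2L1, with 2 adjusted over the list alone (camera adjusted p = 0.761). Of 30 DNA repair genes, 5 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.537); XRCC2 and ATM rose by 0.82 and 0.72, and TIMELESS and CHEK1 fell by 0.54 and 0.38. Of 29 p53 targets, 6 rose and 3 fell, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.473, towards higher levels with a mean of 0.29 and a median of -0.03; the mean of the 28 genes other than SPATA18 was 0.03). The kinase gene PLK2 rose by 0.93 and FAS fell by 0.59. SPATA18 had no count in either control and 11 and 33 counts in the knockdown libraries, at least 7.21-fold higher against a floor of 3 counts per control library. On the log2 scale the rise was at least 3.46 without knockdown replicate 1 and at least 1.77 without knockdown replicate 2, and the call was lost without control replicate 1 or 2 (edgeR adjusted p = 0.066 and 0.0883).

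Of 32 type I interferon genes, 3 rose and 3 fell, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.881); OAS2 rose by 1.66, and BST2 and IFIT1 fell by 2.23 and 1.29. BST2 had 30 and 40 counts in the controls and 13 and 2 in the knockdown libraries. Its fall was 4.70-fold, and 2.82-fold without knockdown replicate 2. Without knockdown replicate 1 the fall was 16.3-fold, which rests on 2 counts, fewer than the 3 used as a floor. The call of BST2 was lost without control replicate 1 or 2. Of 15 replication-dependent histone genes, H2BC21 and H1-4 rose by 1.49 and 1.45 on the log2 scale, with 0 adjusted over the list alone (camera adjusted p = 0.327). H2BC21 was at 2.39 without control replicate 2 and 0.88 without knockdown replicate 2, with its call lost without control replicate 1 or 2 (edgeR adjusted p = 0.278 and 0.0605). H1-4 was at 0.71 without knockdown replicate 2 and then not called (edgeR adjusted p = 0.336), nor without control replicate 1 or 2 (edgeR adjusted p = 0.304 and 0.191). Of 31 ribosome biogenesis and MYC targets, 2 rose and 1 fell, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.358), POLR1A, the catalytic subunit gene of RNA polymerase I, by 0.57 and UTP20 by 0.71, with BOP1 lower. Of 22 glycolysis genes, SLC2A1 rose by 0.44 and HK1, PFKL and PFKP fell, the same numbers adjusted over the list alone (camera adjusted p = 0.455). Of 20 endoplasmic reticulum chaperone genes, DNAJB9 rose by 0.96 and CRELD2, HERPUD1 and SDF2L1 fell, again with 1 and 3 adjusted over the list alone (camera adjusted p = 0.881).

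Of 18 heat shock genes, HSPA4L and HSPB1 fell (2 adjusted over the list alone, camera adjusted p = 0.455). Of 21 NRF2 targets, OSGIN1 rose by 0.62 and the cystine transporter gene SLC7A11 fell by 1.15 (1 and 1 adjusted over the list alone, camera adjusted p = 0.966). Of 12 fatty acid synthesis genes, the transcription factor gene SREBF1 fell by 0.94 and ACSS2 by 0.66 (2 adjusted over the list alone, camera adjusted p = 0.358 towards lower levels, with a mean of -0.15 and a median of 0.01). Of 17 nuclear ATP synthase genes, ATP5F1D and ATP5ME fell (2 adjusted over the list alone, camera adjusted p = 0.358). Median, mean and camera direction also differed in sign for the hnRNP family, mitosis and NRF2 lists.

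Of 4 genes reported as RALY targets, 2 fell, and the same number when adjusted over the list alone. E2F1, a cell cycle transcription factor, had 64.0 ± 1.38 CPM in the controls and 39.9 ± 8.09 CPM in the knockdown (log2 fold change -0.68, SE 0.147, edgeR adjusted p = 0.00579). The linker histone gene H1-10 fell by 0.45 on the log2 scale (edgeR adjusted p = 0.0131). ANXA1 and PRMT1 had log2 fold changes of -0.09 and -0.19 (edgeR adjusted p = 0.612 and 0.263), at occupancies of 79.3% and 80.9%, where counts had levelled off.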

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

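The offsets that follow occupancy or GC content and length, and the correction for levelling off, were chosen after seeing the data. RALY stayed called in each of the 15 gene-level alternatives, and no gene called in the comparison was called in the opposite direction in any of them. The log2 fold change of RALY ran from -1.96 to -1.76 over the libraries left out. Leaving out 1 library gave 340 to 2908 genes higher, 508 to 3351 lower and 10 to 21 lists called by camera; the lone library of the reduced group is then assumed to vary like the other group. Against a minimum fold of 1.2, 1480 genes were higher and 1604 lower, since that test asks for more than a difference from 0. Camera called 8 lists on saturation-corrected counts (the cause was not tested), and 0 with an estimated correlation, where 2 residual degrees of freedom are left. Fry called 1 list, the TGF-beta and YAP targets.

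With the replicate number as a replicate block, 3518 genes were higher and 3536 lower. Deviations of same-numbered libraries correlated at 0.239 over genes, and no label ties a number to a shared day. GC and length offsets gave 2288 genes higher and 3112 lower, with 20 of 137 named calls lost, and together with the replicate block 2967 higher and 3998 lower (the cause was not tested). Without them, 213 genes were higher and 784 lower among those with a GC content over 60%, against 441 and 237 at up to 40%. Of the named genes not called in the comparison, SNRPA was called as lower with the block, saturation-corrected counts and occupancy-trended offsets (adjusted p from 0.0216 to 0.043), and SNRPE with the block, without knockdown replicate 1 and with GC and length offsets, with and without the block (adjusted p from 0.00638 to 0.0427). The genes that changed sign were not called in any of these settings. They were HNRNPC, at -0.036 with GC and length offsets and -0.025 with the block added, and AHCY, at 0.0045 and 0.012. Over the libraries left out, log2 fold changes ran from -0.41 to 0.10 for MT-ND3, from -0.10 to 0.19 for HNRNPC and from -0.15 to 0.079 for AHCY.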

Other observations

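The genes and groups of the first 2 paragraphs were singled out, and the tests of the 3 patterns after them and Fisher's test chosen, after the values were seen; ZEB1, VIM and CDH1 belong to lists fixed earlier, and leaving out each library was also fixed earlier. HOXA3, a developmental transcription factor gene, rose 4.71-fold in the knockdown, from 18.6 ± 0.324 to 87.6 ± 7.20 CPM (SD, n = 2 each; edgeR adjusted p = 2.85e-06), and HOXA2 and HOXA4 of the same cluster rose by 1.26 and 1.33 on the log2 scale. Among 347 protein-coding genes with ZNF symbols, which encode zinc finger proteins, 104 rose and 22 fell, against 1766 and 2191 of the other protein-coding genes called (Fisher's exact test, two-sided, p = 8.79e-18, across genes, which are not independent). ZNF transcripts are GC-poor (median 44.6%), and with GC and length offsets 94 rose and 29 fell. Without control replicate 1 these numbers were 20 and 7, and without control replicate 2 they were 24 and 4.

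MIR200CHG, the host transcript of microRNAs of the miR-200 family, which repress ZEB1, had a log2 fold change of -1.90 (SE 0.349, edgeR adjusted p = 0.00233), and ZEB1, a mesenchymal transcription factor gene, rose from 21.7 ± 3.12 to 55.7 ± 6.84 CPM (log2 fold change 1.36, edgeR adjusted p = 0.000142). CDH1, the E-cadherin gene, had a log2 fold change of -0.36 (edgeR adjusted p = 0.114), and VIM, which encodes vimentin, rose by 0.59. The nuclear noncoding RNA NEAT1 rose 2.02-fold, from 283 ± 26.1 to 571 ± 219 CPM (edgeR adjusted p = 0.00491). Among 2901 long noncoding RNA genes tested, 330 rose and 265 fell, but the balance turned with GC and length offsets (355 and 398), with offsets that follow occupancy (264 and 273) and without control replicate 1 (27 and 40). Without control replicate 2, 42 rose and 20 fell. Among 970 processed pseudogenes, whose reads can be shared with the parent genes, 101 rose and 21 fell, with GC and length offsets 102 and 36, and 12 and 0 or 15 and 0 without control replicate 1 or 2.

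Counts of abundant genes levelled off: MT-ATP6 had 1381, 1387, 1383 and 1380 counts although the library totals differed up to 1.26-fold. MT-ATP6 was the flattest of the genes looked at, and GAPDH differed up to 1.127-fold. Counts of the 13 mitochondrially encoded genes together differed up to 1.035-fold. At an occupancy of 10 to 20%, 33.1% of genes were called, against 6.25% at 50 to 70%. The first test asked whether 649 genes with at least 1000 counts and an occupancy of at least 50% varied less between the controls than counting allows, as counting reads with a shared start once was taken to predict; they varied 2.81 times as much as Poisson counting, above the bound set for it. Genes under 20% occupancy with the same counts varied 5.25 times as much, so variation between libraries adds to both values and that bound was too strict, which leaves removal of such reads open. A second test, added after this outcome, compared the ratio of the control libraries: its median was 1.11 (95% bootstrap interval 1.11 to 1.12) at high and 1.30 (1.29 to 1.31) at low occupancy, consistent with a limit on counts per base, and the knockdown pair gave 1.05 and 1.19. After correction for levelling off, the SD of log2 fold changes at high occupancy was still 0.617 times that at low occupancy. Genes with an occupancy, as a fraction, of 0.9 or more in any library are left out of that value. Abundant genes may also respond less, or the correction may be incomplete.

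Small nucleolar RNA genes were higher in the knockdown: 37 of 196 rose and 2 fell, with a median log2 fold change of 0.54 (95% bootstrap interval 0.46 to 0.63) and a median level of 2.73 CPM. For more unspliced intronic reads, microRNA genes were taken as a gauge and had a median of 0.079 (interval -0.01 to 0.14). Which of them lie in introns was not checked, so this cannot decide and leaves such reads open. Host genes had a median of 0.14 (0.23 without control replicate 1, -0.01 without control replicate 2 and 0.05 with GC and length offsets; 0.16, interval 0.09 to 0.23, in the 66 hosts with saturation-corrected counts; 0.26, -0.02 to 0.35, in the 15 under 20% occupancy), and a second test, added because most hosts had levelled off, took each small nucleolar RNA minus its own host: the median difference was 0.44 (0.08 to 0.60) for hosts under 20% occupancy and 0.30 (0.18 to 0.50) with corrected hosts, which argues against a host rise as the whole cause and leaves a part open. Better recovery of short RNAs stays open too, as 19 mitochondrial transfer RNA genes had a median of 0.14 with a wide interval (-0.03 to 0.36), 0.25 without control replicate 2 and -0.27 with GC and length offsets. With GC and length offsets the small nucleolar RNA median fell to 0.18, with 13 higher and 5 lower, but these genes are 38.8% of all tested genes of their length and so set part of the trend that was removed; GC content or length and a change of the RNAs themselves cannot be told apart here.

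Of the 38 tested members of the TGF-beta and YAP or the mesenchymal and matrix list, 29 rose; this was 18 without control replicate 1 and 16 without control replicate 2. GC and length offsets left 29 members higher and saturation-corrected counts 28, which argues against either as the whole cause. For fibroblast-like cells in the knockdown cultures, a first test set the highest level of COL1A1, COL1A2 and COL3A1 in the knockdown, 95.5 CPM for COL1A1, against the rise of CCN2 of 97.0 CPM, and could not decide, since COL1A1 was also present in the controls. A second test, added for that reason, used the rise: among these 3 collagens the largest was 0.30 CPM, for COL3A1, and COL1A2 stayed at 0.0672 CPM in the knockdown, which argues against such cells as the main source, although COL6A3, a marker present in the controls at 73.9 CPM, rose to 119.9 CPM. A response to RALY depletion stays a hypothesis, and effects of lentiviral handling, of the unclear control treatment or of hairpin off-targets were not tested.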
